A study of Mus musculus with 4 samples.

How the data were processed

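RNA from Arf-null mouse ES cell lines, infected with a retroviral vector for miR-205 and GFP or for GFP alone, was measured on Affymetrix arrays, 1 array for each of 4 groups (each vector at day 0 and day 4). Per the labels, RNA was extracted with Trizol, and biotin-labelled cRNA was made with the 2-cycle protocol of the manufacturer. The header of the deposited probe table names the Mouse Gene 1.0 ST array. The deposited values are log2 expression per probe set, normalized between arrays by RMA by the authors. The labels also name Partek 6.6, and the role and order of the tools are not given in the sources used here. The values ran from 3.07 to 14.7. Arrays give no counts, and their number limits the precision.

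Of 35556 probe sets, 21789 name 1 gene symbol, 1621 name several and 12146 are unnamed here; only the first kind was used for genes, giving 19938 genes. For the 999 genes with 2 or more probe sets the probe set with the highest mean was read. Chromosomes came from a gene table joined by gene identifier, which held 21698 of the named probe sets. The genome build of the array design is not given in the sources used here, so no coordinates are printed and chromosomes serve as groups of genes.

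Each comparison is the difference of log2 values of 2 arrays: miR-205 minus GFP at day 0 and at day 4, embryoid bodies minus ES cells for each vector, and the day 4 difference minus the day 0 difference. A gene was called at a difference of at least 2-fold with the brighter array at or above its own median over all probe sets. With 1 array per group no test between groups was run. An additive fit of vector and day over the 4 arrays would leave 1 residual degree of freedom and take the difference between days as noise, and it was not run. As a partial measure of noise, the robust standard deviation between probe sets of a gene was 0.0751 at day 0 and 0.0553 at day 4, and 0.119 and 0.0964 for pairs whose levels differed by more than 0.5, chosen after seeing the data because pairs of like level may share probes. For the courses of the GFP and miR-205 lines it was 0.138 and 0.161, and 0.269 and 0.342 for pairs of unlike level. It leaves out the spread between cultures and infections. The procedure was tested on simulated data with planted changes, where it called 49 of 50 genes changed 2.5-fold at day 0, 50 of 50 at day 4, 40 of 50 in the GFP course and 42 of 50 in the miR-205 course. Of genes changed 1.5-fold it called 0 of 50 on either day, 6 of 50 in the GFP course and 5 of 50 in the miR-205 course. Of 19738 unchanged genes it called 0 on either day, 3 in the GFP course and 53 in the miR-205 course, where the noise put in was larger. The simulated noise was only that between probe sets of unlike level. Changes were planted only in genes at least 0.5 above the floor. These counts therefore give no rate of false calls between cultures, infections or single arrays.

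The call rule, the comparisons, 23 gene lists, the rule for naming genes and the alternative settings were set before the data were examined. The lists cover extraembryonic endoderm, basement membrane and parietal endoderm, pluripotency, primed epiblast and neurectoderm, primitive streak and mesoderm, trophoblast, reported miR-205 targets, epithelial junctions, integrins and focal adhesion, other adhesion molecules, mesenchymal genes, fibroblast markers, primitive blood and endothelium, p53 targets, proliferation, immediate early and stress genes, interferon response, hypoxia and glycolysis, sterol synthesis, imprinted genes, two-cell-like genes, sex-linked genes and housekeeping genes. A list's median was ranked among 10000 random lists matched on deciles of mean expression, where at least 5 genes were measured. The random lists draw genes singly, so they ignore that genes of a list may vary together. The percentile also leaves out the spread between cultures and is no p-value. Named genes were the 10 largest per direction of each vector comparison, 8 for each course and 5 for the subtraction between days, whose probe sets above the floor differ the same way, with up to 4 members of each list, members of lists with 5 or fewer calls, and 20 fixed genes. Beyond this rule some genes were named after their values were seen: at day 4 Apoa1, Rbp4, Hnf4a, Pdgfra, Cited1, Fst, Foxa2, Lrp2, Apoa2, Cdh5, Tek, Etv2, Gata1, Tal1, Vim, Cdh3 and the fibrillar collagens, in the GFP course Fgf4 and Lin28a, and the genes called on both days. So were Tfap2c and Evx1 at day 4.

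Alternatives were the mean over probe sets, a loess of each difference on level (span 0.3), centring each array on its median, quantile normalization, no floor, a floor at the 75th percentile, a 3-fold rule and random lists also matched on the number of probe sets. Counts without X-linked genes were chosen after seeing the data. Not run were the miR-205 seed sites with their 4 alternatives, since the reference holds no untranslated region sequences, and the removal of probe sets by suffix, since the identifiers are plain numbers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.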

Results

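Gene expression was measured on 4 microarrays from mouse embryonic stem (ES) cells that lack the Arf tumour suppressor. The cells carried a retroviral vector for the microRNA miR-205 with green fluorescent protein (GFP), or a vector for GFP alone, and were sorted for GFP. Each infected line was measured as undifferentiated ES cells (day 0), grown with the cytokine LIF, and as embryoid bodies (day 4), aggregates formed after LIF was withdrawn. There was 1 array per group and there were no replicates, so values carry no error between cultures, no p-value was computed, and the number of arrays limits the precision. Values are log2 expression, and differences are given on the log2 scale with the fold in places. A gene was called higher or lower when it differed by at least 2-fold and its brighter array lay at or above that array's median. The array medians over 35556 probe sets were 6.89 and 6.92 at day 0 (GFP and miR-205) and 6.63 and 6.64 at day 4. Across genes, which are not independent replicates, the pairs of arrays from the same day correlated at 0.993 (day 0) and 0.990 (day 4), and the pairs from the same line at 0.962 (GFP) and 0.949 (miR-205).

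The vectors themselves could not be read from the arrays. The probe set of Mir205 (10361265), singled out after its values were seen, lay below the array median on the 4 arrays and differed between the vectors by 0.04 at day 0 and 0.23 at day 4. Cdkn2a, the locus that encodes Arf and also p16Ink4a, read 6.46 and 6.32 at day 0 and 6.54 and 6.45 at day 4 (GFP and miR-205). Of 23 gene lists, that of sex-linked genes had 4 measured members (Xist, Eif2s3y, Kdm5d and Uty), which lay below the array median on the 4 arrays and differed by a median of 0.01 at day 0 and -0.00 at day 4.

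The day 0 comparison asks what miR-205 did in undifferentiated cells. With miR-205, 23 genes were higher and 36 lower of 11160 above the floor, a small set next to the later comparisons. Cubn, an endocytic receptor of visceral endoderm (probe set 10480155, chromosome 2), was higher by 1.77 (3.41-fold), from a GFP level below the floor, against which it was 2.76-fold higher. The guidance cue Ntn1 was higher by 1.75 and Tmem267 by 1.63. Also higher were Pla2g7, which hydrolyses platelet-activating factor (2.79-fold), the calcium pump Atp2a3 (1.36), the urokinase receptor Plaur (1.33), the guidance receptor Robo4 (1.23), Igsf21 (1.23), the proteoglycan serglycin, Srgn (1.21), and transferrin, Trf (1.19). Lower were Nxf3, of the RNA export factor family (-2.61), Gm9 (-2.57), 1700018B24Rik (-1.85), the ubiquitin ligase adaptor Klhl13 (-1.75), Igfbp7 (-1.69), Pnma5 (-1.68), the Polycomb-group gene Scml2 (-1.64), the phosphatase subunit Ppp2r2c (-1.61), Taf9b (-1.58) and the reproductive homeobox gene Rhox9 (-1.57). Of these, Gm9, 1700018B24Rik, Pnma5, Scml2 and Ppp2r2c lay below the floor on the miR-205 array, as did 12 of the 36 lower genes, so their sizes and order rest on background, and against the floor itself they were lower by 5.17-fold, 2.84-fold, 2.37-fold, 2.01-fold and 1.61-fold. Of the 36 lower genes, 16 were X-linked (44.4%, against 3.22% of the genes above the floor), among them Nxf3, Gm9, Klhl13, Pnma5, Scml2, Taf9b and Rhox9, and none of the 23 higher genes was. The median of 411 X-linked genes minus the autosomal median was -0.30, and 353 of them lay below the autosomal median.

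Few of the lineage genes were called at day 0. Genes below the floor on both arrays could not be called but enter the medians. They include 6 of 21 extraembryonic endoderm and 7 of 13 trophoblast genes. Of 21 extraembryonic endoderm genes, Cubn alone passed the rule, and the list median was 0.12 (percentile 97.9 among 10000 random lists matched on expression). The Gata4 and Gata6 regulators of this lineage differed by 0.01 and -0.00, and the endocytic receptor Lrp2 by 0.90 and the adaptor Dab2 by 0.65, without passing. None of 15 basement membrane genes passed, with a median of 0.20 (percentile 99.96), 0.74 for the laminin chain Lama1, 0.68 for Lama5 and 0.58 for the collagen chain Col4a1. Among 11 primed epiblast and neurectoderm genes the homeobox gene Otx2 was higher (1.15) and the median was 0.17 (98.2). Among 13 trophoblast genes the imprinted gene Peg10 was higher (1.12) against a median of -0.09 (10.4), and of 13 imprinted genes Sgce, the neighbour of Peg10, was higher (1.02) against a median of 0.05 (78.5).

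The remaining lists held no called gene at day 0. The pluripotency list of 23 genes had a median of -0.05 (percentile 20.2), with -0.29 for Pou5f1, -0.50 for Nanog and -0.12 for Sox2, the core factors of the pluripotent state, and -0.92 for Dppa3. The 18 genes reported elsewhere as miR-205 targets had a median of -0.06 (14.8), with Zeb1 at -0.23, Zeb2 at 0.08 and Inppl1 at -0.05. The adhesion lists had medians of 0.04 for 22 epithelial junction genes (80.5), with the cadherin Cdh1 at 0.20, of 0.05 for 25 integrin and focal adhesion genes (86.4), and of 0.06 for 22 other adhesion molecules (85.8). Below most random lists lay sterol synthesis (11 genes, -0.23, percentile 0.27), hypoxia and glycolysis (14 genes, -0.17, 0.67), proliferation (19 genes, -0.15, 0.96) and the mesenchymal list (12 genes, -0.16, 1.51). Of the 12 mesenchymal genes 5 lay below the floor on both arrays, so that list's median rests partly on background. The medians were 0.10 for p53 targets (91.9), -0.07 for immediate early and stress genes (15.6), 0.01 for the interferon response (52.6), -0.01 for primitive streak and mesoderm (47.7), -0.03 for primitive blood and endothelium (37.2), -0.04 for fibroblast markers (22.4), 0.03 for two-cell-like genes (55.9) and -0.08 for housekeeping genes (20.8). Below the floor on both arrays lay 12 of 13 blood and endothelium genes, 10 of 15 streak and mesoderm genes and 9 of 15 fibroblast markers. So did 7 of 12 interferon genes, 5 of 5 two-cell-like genes and 13 of 22 other adhesion molecules. The medians and percentiles of these lists therefore rest largely on background and do not show a lack of difference. The lists share some genes and are not independent, and 23 lists were read in 5 comparisons. Random lists draw genes singly, while genes of a list may vary together, so an extreme percentile is no measure of significance.

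**Figure D1:**
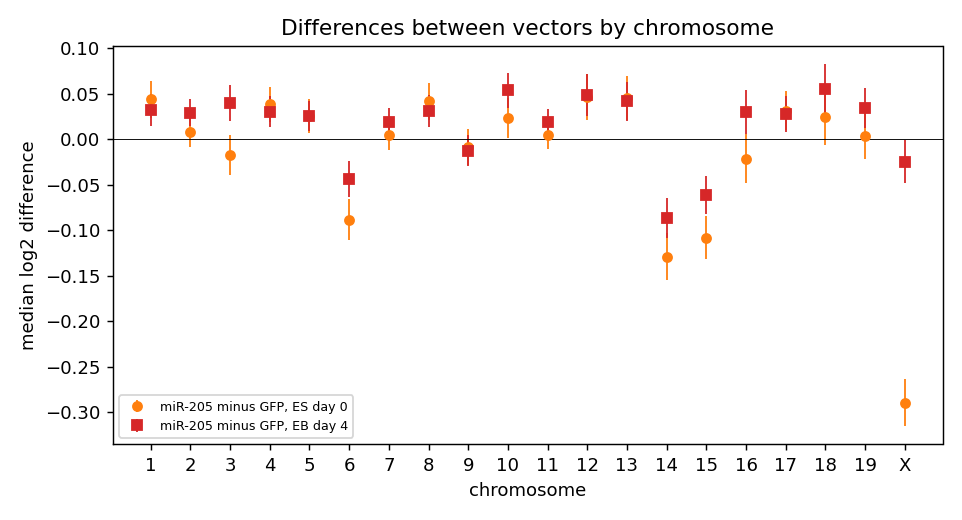
Median log2 difference between miR-205 and GFP of the genes of each chromosome, at day 0 (circles) and day 4 (squares), with bars of 2 standard deviations of random gene sets of the same size to each side. The X chromosome lies at -0.29 at day 0 and -0.02 at day 4, and chromosomes 6, 14 and 15 lie below 0 on both days.

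By chromosome, genes of chromosomes 14, 15 and 6 were slightly lower with miR-205 at day 0 (medians -0.13, -0.11 and -0.09) and at day 4 (-0.09, -0.06 and -0.04), each below all 10000 random sets. Chromosomes 1, 4, 8, 12 and 13 were shifted the other way at day 0 (0.04, 0.04, 0.04, 0.05 and 0.05, percentiles 99.97 to 100), and chromosome 10 at day 4 (0.05, 99.95). Chromosome 9 was slightly lower at day 4 (-0.01, 0.04). These shifts are far smaller than a 2-fold call. The random sets were drawn from all genes above the floor. They include genes of X and of chromosomes 6, 14 and 15, which lowers the reference for the other chromosomes. The shifts of chromosomes 6, 14 and 15 did not span the chromosomes, and chromosomes 1, 4, 8, 9, 10, 12 and 13 were not split. With the genes of 6, 14 and 15 each split in order into 4 equal parts and compared with the other autosomes, the day 0 shifts were 0.07, -0.01, -0.14 and -0.29 on chromosome 6, -0.14, -0.22, -0.25 and 0.09 on 14, and -0.01, -0.14, -0.18 and -0.13 on 15. Nanog and Dppa3 of the pluripotency list lie on chromosome 6, and which of its parts hold them is not given here.

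The day 4 comparison asks what miR-205 did as the cells differentiated. With miR-205, 227 genes were higher and 41 lower of 11918 above the floor, and 25 were higher and 1 lower (Gm5662, dim with miR-205) by 4-fold or more as measured. Among genes above the floor on both arrays, the largest were the semaphorin and VEGF co-receptor Nrp1 (3.03), the thyroxine carrier transthyretin, Ttr (2.89), the hyaluronan link protein Hapln1 (2.55) and the mesenchymal cadherin Cdh11 (2.43). Larger or similar differences were measured for genes that lay below the floor on the GFP array, where the size rests on background: the embryonic globins Hbb-bh1 (probe set 10566268, chromosome 7; 4.45) and Hbb-y (3.45), the matrix protein periostin, Postn (3.63), the tryptophan oxygenase Tdo2 (2.77), the heart T-box factor Tbx20 (2.74) and the growth factor Bmp5 (2.74). Against the floor itself Hbb-bh1 was 8.12-fold higher, Tbx20 5.72-fold, Postn 4.36-fold, Hbb-y 4.21-fold, Bmp5 2.52-fold and Tdo2 1.77-fold. The GFP array was below its floor for 68 of the 227 higher genes.

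Extraembryonic endoderm genes were higher as a group in the miR-205 embryoid bodies. Of 21 measured, 14 passed the rule and 21 were positive, with a median of 1.29 (2.45-fold, percentile 100). After Ttr these were the lipoprotein Apob (2.29), the lineage regulator Gata6 (1.85), Cubn (1.80), Apoa1 (1.64), the retinol carrier Rbp4 (1.60), the nuclear receptor Hnf4a (1.57), the growth factor receptor Pdgfra (1.51), alpha-fetoprotein, Afp (2.79-fold), Dab2 (1.45), Cited1 (1.29), Sox17 (1.26), follistatin, Fst (1.11), and Gata4 (1.10). Afp lay slightly below the floor on the GFP array (6.55). Sox7 at 0.62, Foxa2 at 0.53 and Lrp2 at 0.69 did not pass. Apoa1, Rbp4, Hnf4a, Pdgfra, Cited1, Fst, Foxa2 and Lrp2 were picked for naming here after their values were seen. Of 15 basement membrane and parietal endoderm genes, the plasminogen activator Plat (1.20) and Col4a1 (1.03) passed, with a median of 0.58 (100) and Lama1 at 0.75.

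**Figure D2:**
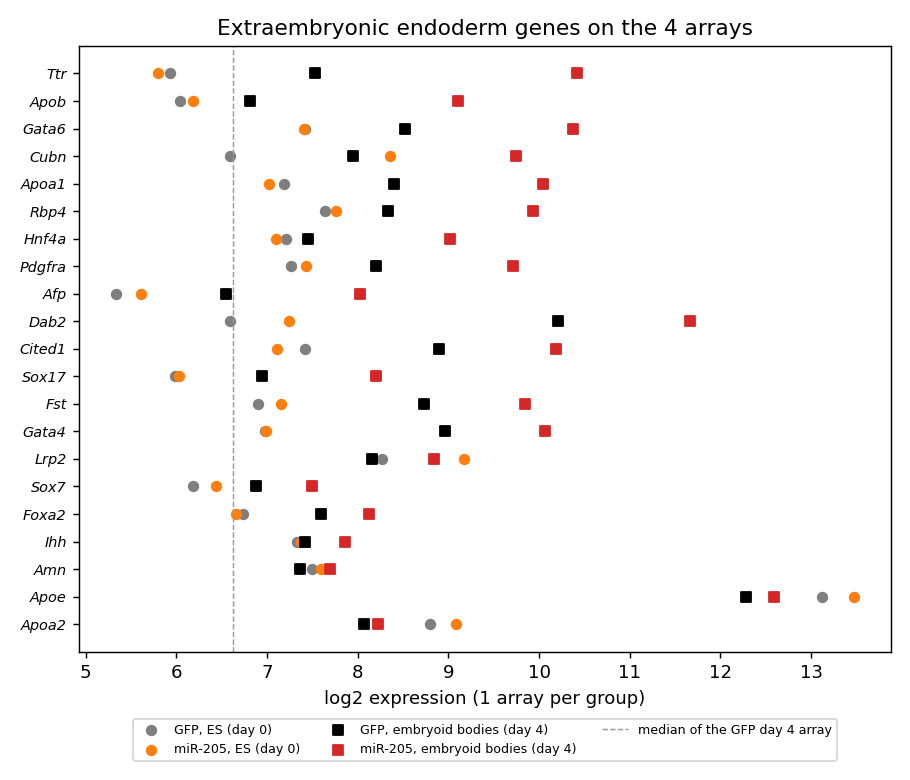
Log2 expression of the 21 measured extraembryonic endoderm genes on the 4 arrays, 1 point per array (circles at day 0, squares at day 4). At day 4 the miR-205 array lies above the GFP array for all 21, by 2.89 for Ttr and by 0.15 for Apoa2.

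Blood and vessel genes were higher too, with a few genes of mesoderm and trophoblast. Of 13 primitive blood and endothelium genes, 7 passed and 13 were positive (median 1.06, percentile 100), namely the globins Hbb-bh1, Hbb-y and Hba-x (2.37), the VEGF receptor Kdr (2.08), the endothelial cadherin Cdh5 (1.58), the angiopoietin receptor Tek (1.34) and the vascular regulator Etv2 (1.06). Like Hbb-bh1 and Hbb-y, Hba-x lay below the floor on the GFP array, and against the floor itself it was 4.83-fold higher. The blood regulators Gata1 and Tal1 differed by 0.08 and 0.18, and these with Cdh5, Tek and Etv2 were likewise picked after their values were seen. Of 15 primitive streak and mesoderm genes, the forkhead factor Foxf1 (2.22) and the homeobox gene Mixl1 (1.49) passed, with a median of 0.19 (99.5). Below the floor on both arrays lay 5 of the 15, among them Evx1, whose difference is this median. Foxf1 lay below the floor on the GFP array (6.35), so its size rests on background. The streak marker T had no probe set here. Of 13 trophoblast genes, Hand1 (2.40), which also marks lateral mesoderm, Cdx2 (1.10) and the keratin Krt8 (1.07) passed, with a median of 0.60 (100). This list was split, with 7 positive and 6 negative, among the latter Tfap2c (-0.67). Cdx2 read 5.57 on the GFP array, below the floor, and 6.67 with miR-205, close to the floor of 6.64, so its size rests on background. Of 11 primed epiblast and neurectoderm genes, the cadherin Cdh2 passed (1.04), with a median of 0.35 (99.98) and Fgf5 at 0.89.

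Adhesion and mesenchymal genes differed unevenly at day 4. Of 12 mesenchymal genes, 6 were higher (median 0.84, percentile 100): Cdh11, the matrix protease Mmp2 (1.67), the transcription factors Zeb2 (1.63) and Snai2 (1.51), vimentin, Vim (1.10), and Cdh2. Zeb2 and Snai2 lay below the floor on the GFP array, so their sizes rest on background. Fibroblast markers moved alongside, with 5 of 15 higher (median 0.43, 100), namely Postn, the smooth muscle actin Acta2 (2.43), the receptor Pdgfrb (2.36), Twist2 (1.59) and decorin, Dcn (1.05), while the fibrillar collagens Col1a1, Col1a2, Col3a1 and Col5a1 gave 0.73, 0.92, 0.03 and 0.15. Like Postn, the genes Pdgfrb, Twist2 and Dcn lay below the floor on the GFP array, so their sizes rest on background. Of 22 other adhesion molecules, Cdh11, the matrix protein tenascin, Tnc (2.17), the protocadherins Pcdh7 (1.87) and Pcdh18 (1.87) and Flrt2 (1.52) were higher (median 0.29, 100). Tnc, Pcdh7 and Flrt2 lay below the floor on the GFP array, so their sizes rest on background, and Pcdh18 lay just below it. Of 25 integrin and focal adhesion genes, Itga8 was higher (1.41), with a median of 0.21 (100) and Itgb3 at -0.95. Itga8 read 5.42 on the GFP array, below the floor, and 6.83 with miR-205, close to the floor of 6.64, so its size rests on background. None of 22 epithelial junction genes passed, though 19 were positive (median 0.25, 100), with Cdh1 at 0.41, the desmosomal cadherin Dsc2 at 0.93 and the cadherin Cdh3 at -0.75.

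None of the genes reported as miR-205 targets was called lower. This does not show that none was lowered, since the 2-fold rule called 0 of 50 simulated genes changed 1.5-fold at day 4. Of the 18 measured at day 4, Zeb2 (1.63) and the X-linked junction protein Amot (1.09) were higher, with a median of 0.19 (percentile 99.9). The size for Zeb2 rests on background, since it lay below the floor on the GFP array. Zeb1, a repressor of Cdh1, differed by -0.06, the lipid phosphatase Inppl1 by 0.19 and the receptor Erbb3 by -0.68. Of 23 pluripotency genes none passed and 19 were negative (median -0.23, percentile 0), with Pou5f1 at -0.18, Nanog at -0.40, Sox2 at -0.22 and Dppa3 at -0.99. Of 13 imprinted genes, the noncoding RNA Meg3 (1.66), the growth factor Igf2 (1.38), Sgce (1.19) and Mest (1.15) were higher (median 0.68, 100).

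The 41 lower genes at day 4 included genes of the germ line. Those with the largest measured differences were Gm5662 (-2.30), Rhox6 (-1.93), Rhox9 (-1.82), Gm9 (-1.77), Scml2 (-1.61), the germ cell RNA-binding protein Dazl (-1.56), the oocyte gene Nlrp4c (-1.55), Rhox1 (-1.48), the germ cell gene Asz1 (-1.44) and Ccdc152 (-1.39). On the miR-205 array Gm5662, Scml2, Nlrp4c, Asz1 and Ccdc152 lay below the floor, as did 15 of the 41, so their sizes and order rest on background, and against the floor itself they were lower by 2.41-fold, 2.19-fold, 1.74-fold, 1.06-fold and 2.08-fold. Of the 41, 9 were X-linked, and so were 19 of the 227 higher. The Rhox genes, the globins and other gene families have close relatives whose transcripts can bind the same probes, which these data cannot separate. Of 5 two-cell-like genes, Zfp352 was lower (-1.02), with a median of -0.32 (0.18). Because 4 of the 5 lay below the floor on both arrays, this median and its percentile rest on background. No gene passed among p53 targets (0.18, percentile 99.1), proliferation genes (-0.08, 1.90), immediate early and stress genes (0.20, 98.9), interferon response genes (0.06, 88.0), hypoxia and glycolysis genes (0.11, 98.2), sterol synthesis genes (0.22, 99.96) and housekeeping genes (-0.03, 33.3).

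**Figure D3:**
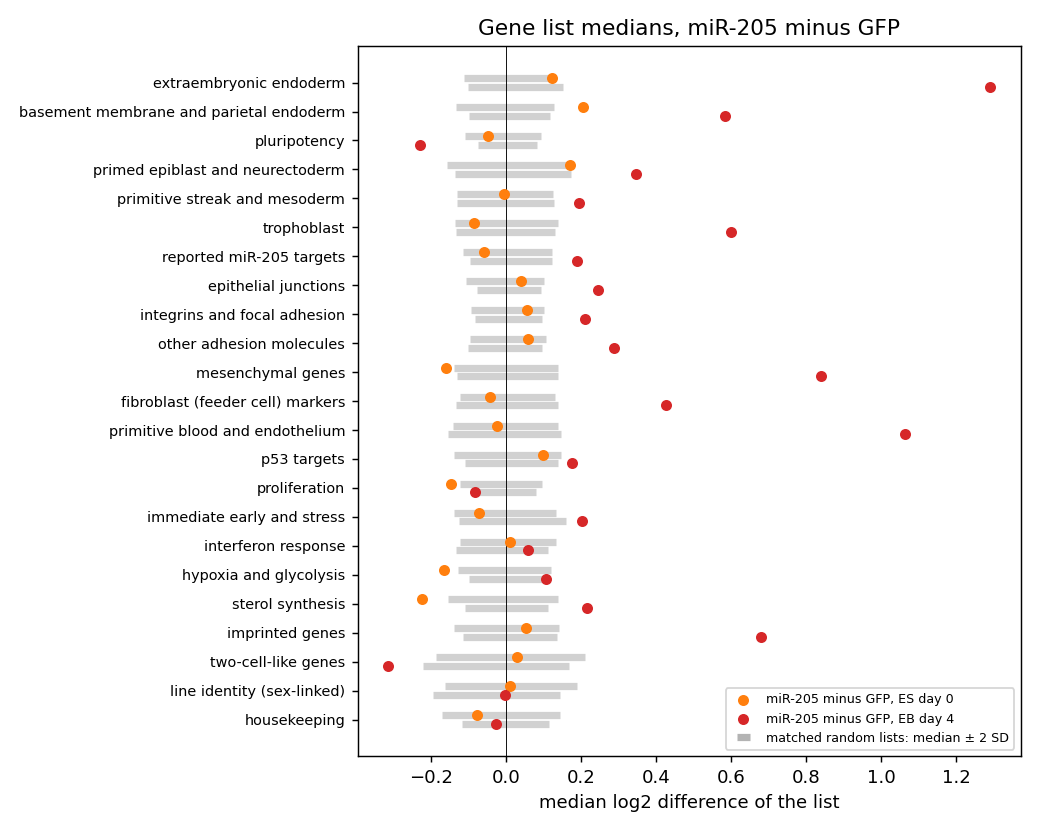
Median log2 difference between miR-205 and GFP of each gene list at day 0 (orange) and day 4 (red), with grey bars for the median of expression-matched random lists and 2 standard deviations to each side. At day 4 extraembryonic endoderm (1.29), primitive blood and endothelium (1.06) and mesenchymal genes (0.84) lie farthest above 0.

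Differentiation in the GFP line gives the control course. From ES cells to embryoid bodies 830 genes rose and 787 fell of 11718 above the floor. The endocytic adaptor Dab2 rose by 3.62, the protease inhibitor Spink1 by 3.61, Dppa3 by 3.46, the keratin Krt18 by 3.37, Amot by 3.26, Rhox9 by 3.19, Gkn2 by 3.15 and the nucleosome-binding gene Hmgn5 by 3.13. Pcolce, an enhancer of collagen processing, fell by 3.78, and Susd2 by 3.25, the protease inhibitor A2m by 3.23, the GABA receptor subunit Gabbr1 by 3.16, the citrate transporter Slc13a5 by 3.08 and Emp1 by 3.01. Snord37 fell 7.99-fold and the anoctamin Ano9 7.97-fold. The dimmer array was below its floor for 174 of the 830 rising genes and 109 of the 787 falling, among them Dab2, Spink1, Amot, Gkn2, Slc13a5 and Snord37, and against the floor itself Dab2 rose 9.98-fold, Amot 6.52-fold, Spink1 2.88-fold and Gkn2 2.55-fold.

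By list, 8 of 21 extraembryonic endoderm genes rose in the GFP line (median 0.94, percentile 100), among them Gata4 (1.99) and Gata6 (1.11). So did 6 of 11 primed epiblast and neurectoderm genes (1.15, 100), with Fgf5 at 2.77 and Otx2 at 2.35, 5 of 13 trophoblast genes (0.91, 100), and 3 of 15 primitive streak and mesoderm genes with 1 falling (0.08, 88.5), with the secreted inhibitor Cer1 at 2.82. At day 0 Cer1 (5.23) and Fgf5 (6.50) lay below the floor, so their sizes rest on background. Below the floor on both arrays lay 7 of the 15 streak and mesoderm genes. Of 13 blood and endothelium genes Cdh5 (2.63) and Kdr (1.52) rose (0.46, 99.99). At day 0, 12 of these 13 lay below the floor on both arrays, so sizes in this list rest largely on background. Of 23 pluripotency genes 2 rose, Dppa3 and Lin28a (1.18), and 4 fell, Klf4 (-2.43), Tbx3 (-1.91), Tdgf1 (-1.50) and Fgf4 (-1.46), with a median of -0.03 (7.33). Pou5f1, Nanog and Sox2 gave 0.33, 0.43 and -0.03. Basement membrane genes split, with 2 rising and 5 falling of 15 (-0.38, 0.99), the proteoglycan Hspg2 at -2.46. Cdh1 fell by 1.36, and of 22 junction genes 5 rose and 4 fell (-0.07, 8.85). Of 25 integrin genes 1 rose and 6 fell (-0.06, 19.6), and of 22 other adhesion molecules 2 rose and 5 fell (0.04, 79.6).

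Of the remaining lists in the GFP line, sterol synthesis had 1 rising and 4 falling of 11 (-0.70, percentile 0.20), with Dhcr7 at -2.10, and proliferation had 2 rising of 19 (0.66, 99.7), with the cyclin Ccnd2 at 1.86. Of 12 mesenchymal genes 2 rose and 2 fell (0.21, 89.7), of 15 fibroblast markers 1 rose and 2 fell (-0.11, 30.2), of 18 reported targets 3 rose and 3 fell (0.18, 68.9), of 13 imprinted genes 3 rose and 2 fell (0.35, 89.8), of 14 hypoxia and glycolysis genes 1 rose (-0.01, 22.1), and of 5 two-cell-like genes 1 rose (0.37, 99.9). Below the floor on both arrays lay 4 of the 5 two-cell-like genes, so their median rests on background. None passed among p53 targets (-0.09, 13.4), immediate early and stress genes (-0.08, 36.4), the interferon response (0.09, 88.6), housekeeping genes (0.22, 45.8) and the sex-linked genes (-0.02).

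The miR-205 line followed a similar course with more genes rising. From ES cells to embryoid bodies 1382 genes rose and 881 fell of 11807 above the floor. Of the rising genes 107 were X-linked, against 48 of the 830 in the GFP line, and the X median minus the autosomal median was 0.29 here and 0.02 in the GFP line, with the lower X-linked levels of the miR-205 day 0 array as the starting point. Hbb-bh1 rose by 5.22, Spink1 by 5.04, Hapln1 by 4.87, Nrp1 by 4.72, the calpain Capn6 by 4.70, Ttr by 4.63, Amot by 4.57 and Fndc3c1 by 4.48 (Capn6, Amot and Fndc3c1 are X-linked), each from below the day 0 floor, so that the sizes and their order rest on background. Against the floor itself Amot rose 13.6-fold, Ttr 11.3-fold, Nrp1 9.58-fold, Fndc3c1 9.38-fold, Capn6 8.73-fold, Spink1 8.72-fold, Hbb-bh1 6.61-fold and Hapln1 5.30-fold. The dimmer array was below its floor for 406 of the 1382 rising genes and 127 of the 881 falling, Obox6 among the latter. The homeobox gene Obox6 fell by 3.68, A2m by 3.62, Pcolce by 3.47, Susd2 by 3.35, Atp2a3 by 3.13, Gabbr1 by 3.12, Gm7265 by 3.05 and the noncoding RNA Malat1 by 3.01. The courses of the lines, which share no array, correlated across 12225 genes at r = 0.89 (rho = 0.89). Among genes above the floor in both, 648 rose in both (91.5 expected of independent lists), 612 fell in both (58.5 expected) and 0 went opposite ways.

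By list, 16 of 21 extraembryonic endoderm genes rose in the miR-205 line (median 2.17, percentile 100), with Dab2 at 4.42, Gata4 at 3.08 and Gata6 at 2.96, and 8 of 13 blood and endothelium genes rose (1.46, 100), 12 of the 13 being below the floor on both day 0 arrays. So did 6 of 12 mesenchymal genes with 1 falling (0.89, 99.99), 7 of 13 trophoblast genes (1.10, 100), 6 of 15 streak and mesoderm genes with 1 falling (0.83, 100), 6 of 11 primed epiblast and neurectoderm genes (1.17, 99.99) and 5 of 15 fibroblast markers with 1 falling (0.71, 100). Of 23 pluripotency genes 2 rose and 5 fell (-0.39, 0.26), with Pou5f1 at 0.43 and Nanog at 0.53. Of 15 basement membrane genes 5 rose and 6 fell (-0.38, 1.42), of 22 junction genes 7 rose and 4 fell (0.36, 81.7), of 25 integrin genes 5 rose and 6 fell (-0.46, 0.010), of 22 other adhesion molecules 6 rose and 5 fell (0.10, 90.8), of 18 reported targets 5 rose and 3 fell (0.37, 89.1), of 13 imprinted genes 5 rose and 2 fell (0.64, 98.5) and of 11 sterol genes 1 rose and 1 fell (-0.19, 7.07).

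Smaller numbers rose, and none fell, in the other lists of the miR-205 line: 3 of 19 proliferation genes (0.86, percentile 99.97), 3 of 14 hypoxia and glycolysis genes (0.20, 58.6), 2 of 14 immediate early and stress genes (0.14, 75.9), 1 of 12 interferon genes (0.22, 98.0), 1 of 9 housekeeping genes (0.41, 69.6), 0 of 13 p53 targets (0.01, 24.1), 0 of 5 two-cell-like genes (0.04, 89.3) and 0 of 4 sex-linked genes (-0.05). All 5 two-cell-like genes lay below the floor on both arrays. The balance of rising and falling genes over time depends on how the arrays are scaled. In the GFP line 51.3% of calls were rises, against 34.4% after a loess correction and 80.2% with each array centred on its median, and in the miR-205 line 61.1% against 44.4%, 83.8% and, after quantile normalization, 47.8%. Centring moved the median of all genes by 0.27 in the GFP line and 0.29 in the miR-205 line. In the GFP line the medians of pluripotency, junction, integrin, fibroblast, p53, immediate early, hypoxia and sex-linked genes turned positive when centred, and that of reported targets turned negative after loess. In the miR-205 line the median of sterol genes turned positive when centred, those of p53 targets and of immediate early genes turned negative after loess, the first also after quantile normalization, and that of sex-linked genes turned positive after loess and when centred.

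The differences between vectors were compared between the days. Subtracting the day 0 difference from the day 4 difference gave 268 genes higher and 35 lower of 12068, of which 36 and 1 were X-linked. Largest as measured were Hbb-bh1 (4.63), Postn (3.61), Hbb-y (3.43), Nrp1 (3.13) and Ttr (3.02), which lay below the floor on both day 0 arrays, and at the other end Pla2g7 (-2.27), Gm5662 (-1.90), Gm7982 (-1.58), Ntn1 (-1.43) and Igsf21 (-1.38). Of the last group Gm5662 and Gm7982 also lay below the floor on both day 0 arrays, and the sizes of these 2 rest on background. By list, the medians and called genes were 1.09 for extraembryonic endoderm (11 higher of 21, percentile 100), 1.02 for mesenchymal genes (6 of 12, 100), 0.998 for blood and endothelium (6 of 13, 100), 0.73 for fibroblast markers (5 of 15, 100), 0.44 for sterol synthesis (0 of 11, 100), 0.38 for imprinted genes (3 of 13, 99.98), 0.29 for hypoxia and glycolysis (0 of 14, 99.96) and 0.25 for trophoblast genes (3 of 13, 99.3). Further medians were 0.24 for basement membrane genes (2 of 15, 99.8), 0.23 for primed epiblast and neurectoderm (1 of 11), 0.21 for streak and mesoderm (2 of 15, 98.5), 0.14 for reported targets (2 of 18, 95.3), 0.12 for other adhesion molecules (5 of 22, 95.0), 0.11 for integrins (1 of 25, 94.7) and 0.15 for junction genes (0 of 22, 98.5).

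No gene was called in this subtraction among pluripotency genes (-0.11, percentile 1.32), immediate early and stress genes (0.27, 99.1), proliferation genes (0.08, 84.3), p53 targets (-0.01, 36.4), interferon genes (-0.01, 50.2), housekeeping genes (0.10, 83.2) and sex-linked genes (-0.06), and Zfp352 alone was lower among two-cell-like genes (-0.32, 1.84). Below the floor even on their brightest array lay 4 of the 5 two-cell-like genes, so their median rests on background. These subtractions have no error and no test, and show sizes only.

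A small set of genes differed the same way on both days. Cubn (1.77 and 1.80), the noncoding RNA Rian (1.06 and 1.31), Sgce (1.02 and 1.19) and the glutamate transporter Slc1a3 (1.01 and 1.09) were higher at day 0 and day 4, 4 genes where 0.210 were expected of independent lists. The GFP array was below its floor for Cubn at day 0 (6.59) and for Rian at day 4 (5.54), so those sizes rest on background. Lower on both days were 9 genes (0.0774 expected), namely Nxf3, Gm9, Pnma5, Scml2, Rhox1, Rhox9 and Ct55, which are X-linked, and 1700018B24Rik and Gpat3. No gene was called in opposite directions. Across 12225 genes the day 0 and day 4 differences correlated at r = 0.25 (rho = 0.24), and of the 227 genes higher at day 4, 134 were positive at day 0. The pairs share the infected lines, and genes are not independent replicates.

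**Figure D4:**
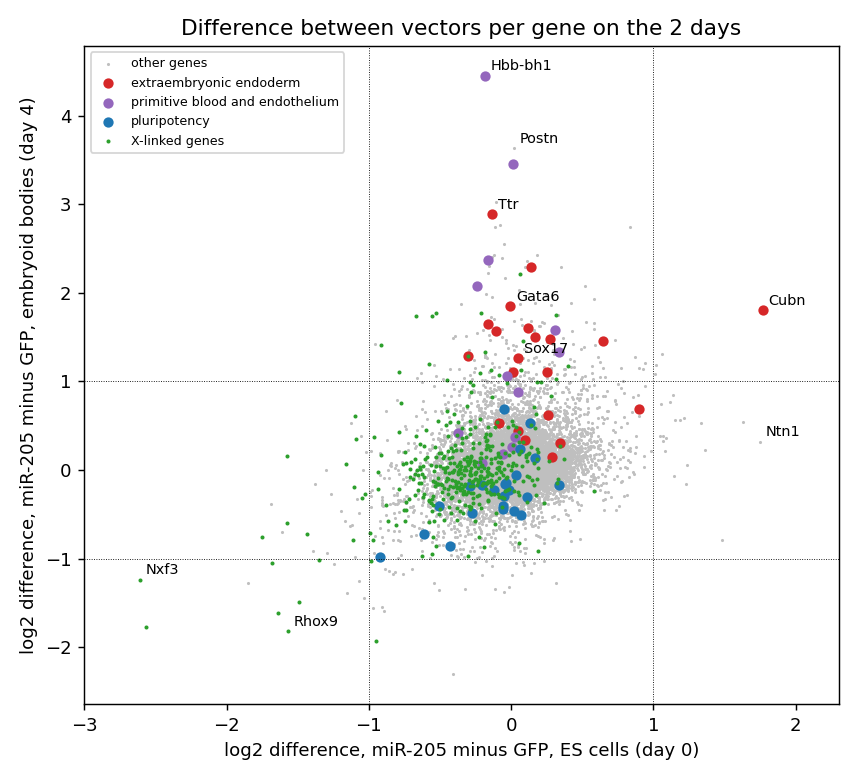
Log2 difference between miR-205 and GFP of each gene above the floor at day 0 (horizontal axis) and day 4 (vertical axis), with dotted lines at 2-fold. Extraembryonic endoderm genes (red) and blood and endothelium genes (purple) lie high at day 4 with most day 0 differences within 0.5 of 0, while Cubn is high on both days (1.77 and 1.80). At day 0, 12 of the 13 blood and endothelium genes lay below the floor on both arrays.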

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

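Chosen only after the result was seen were the tests of level-dependent bias, Xist, the fibrillar collagens (first run on Col3a1 alone), genes picked on the mean course of both lines and other differences between the lines. For chromosomes 6, 14 and 15 the medians, which largely fix the shares, had been seen, but not the parts of the chromosomes.

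Some differences between vectors had opposite signs on the 2 days, and none of these changes was tested; the day 0 sign of Hbb-bh1 is background, since it lay below the floor on both arrays. The change from day 0 to day 4 was 1.02 for the mesenchymal list median, 0.29 for hypoxia and glycolysis, 0.44 for sterol synthesis, 1.37 for Cdh2, 4.63 for Hbb-bh1, -1.38 for Igsf21 and -2.27 for Pla2g7. Of the 12 mesenchymal genes 5 lay below the floor on both day 0 arrays, so the day 0 sign of that list rests partly on background. Among probe sets without a gene name, which the comparisons do not use, 71 were higher and 36 lower with miR-205 at day 0, and 39 higher and 62 lower at day 4.

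X-linked genes were lower on the miR-205 array at day 0, and 353 of 411 lay below the autosomal median. Level-dependent bias between the arrays is argued against, since the X median stayed -0.30 from the autosomal median after a loess correction. A lower X dosage in part of the day 0 cells stays possible, though the shift was -0.04 at day 4 and no genotype was measured. The smallest shift among 4 equal parts of the chromosome was -0.26. With 353 of 411 genes below the autosomal median, this follows largely from the pattern itself. It does not separate dosage from another shift across the chromosome. X inactivation cannot be told apart from a lower dosage, because Xist differed by -0.0822 but lay below the floor on both arrays. That condition was added after Xist was seen there. A direct effect of miR-205 stays open and untested.

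Genes of chromosomes 6, 14 and 15 had slightly lower medians with miR-205 on both days. Level-dependent bias is argued against, since the highest of the 3 medians stayed -0.11 from the other autosomes after loess. The lower medians themselves argue against a few strongly lower genes, which would leave a median near its place. At day 0, 67.7% of the genes lay below the median of the other autosomes. This share follows largely from the medians already seen and is no separate test. A copy number difference in part of the cells cannot be told apart from other explanations, since 8 of 12 parts (4 per chromosome) were lower on both days, between the bounds of 6 and 10 set beforehand. The lower parts were adjacent (the last 2 of chromosome 6, the first 3 of 14 and the last 3 of 15), and the others gave 0.07, -0.01, 0.09 and -0.01 at day 0 and 0.04, -0.02, 0.01 and -0.01 at day 4. A difference limited to part of each chromosome, seen in these same values, stays open without a test of its own, as does an effect of miR-205.

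Of the lineage genes, 14 of 21 for extraembryonic endoderm, 7 of 13 for blood and endothelium and 2 of 15 for primitive streak and mesoderm were higher on the miR-205 array at day 4. Embryoid bodies further along the GFP course cannot be told apart from other explanations. The 830 genes that rose in that line had a median day 4 difference of -0.00 (-0.000755) and the 787 that fell one of 0.09. By the bounds set beforehand both values count against this explanation, but the shared GFP array biases both that way. Genes picked on the mean course of both lines gave 0.11 (1037 rising) and 0.03 (794 falling). Adding them afterwards changed the preset verdict to an open one. Of the 227 higher genes 61 rose in the GFP line, 15 fell and 151 did neither. Fibroblast feeder cells in the miR-205 embryoid bodies cannot be told apart either, although the ES cells had been sorted for GFP. Of the fibrillar collagen genes 0 of 4 were called higher, but Col1a1 and Col1a2 differed by 0.73 and 0.92, more than the noise between probe sets, Col3a1 (0.03) lay near the floor, and 15 of 15 fibroblast markers were positive. With arrays per group at 1, a difference between the infected lines other than miR-205 cannot be told apart from an effect of miR-205.

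The X-linked genes Klhl13 (-1.75 at day 0, -0.75 at day 4) and Dusp9 (-1.05 and -0.32) were singled out after their values were seen.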

How the results depend on the processing

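The counts without X-linked genes were chosen after seeing the data. Under the mean of probe sets, loess and quantile normalization the counts of genes higher and lower in the 5 comparisons stayed within 1.5 times, as they did without a floor, and no named gene with a call took the opposite call. A 3-fold rule, which by construction calls fewer genes, gave 3 higher and 8 lower at day 0, 62 and 5 at day 4, 168 and 203 in the GFP course, 406 and 265 in the miR-205 course and 68 and 2 between days. A floor at the 75th percentile, which leaves fewer genes, gave 21 lower at day 0, 102 higher and 16 lower at day 4, 904 rising in the miR-205 course, and 112 and 21 between days. Centring gave 1809 rising and 447 falling in the GFP course and 2550 and 494 in the miR-205 course; its construction moves each course's differences by 0.27 and 0.29. Without X-linked genes 20 were lower at day 0. The correlation between days was 0.21 with no floor and 0.29 with the 75th percentile floor, and quantile normalization gave medians at day 4 of 1.23 for extraembryonic endoderm and 0.20 for epithelial junctions; the cause was not tested. Of 115 list medians, 100 moved by less than the spread of random lists under loess, 113 under the mean of probe sets, 71 under centring and 101 under quantile normalization; between vectors, medians near 0 took the other sign under at least 1 scaling for interferon, two-cell-like and sex-linked genes at day 0, sex-linked and housekeeping genes at day 4, and p53 targets and interferon genes between days. Of 101 called values of named genes on the 2 days, 101 stayed called under loess, 100 under the mean of probe sets, 99 under centring and 96 under quantile normalization, with 0 opposite, and the 110 list percentiles kept their side with the other matching. No paired analysis of replicates and no omission of a replicate was possible because there was 1 array per group; the seed-site and probe-suffix alternatives were not run. Signal over background limits the folds of genes whose dimmer array lay below its floor: 1 of 23 higher and 12 of 36 lower at day 0, 68 of 227 and 15 of 41 at day 4, 174 of 830 and 109 of 787 in the GFP course, and 406 of 1382 and 127 of 881 in the miR-205 course.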

Other observations

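No test here was chosen after its result was seen: the genes of both tests were listed before their values were seen, but after the patterns that prompted them.

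At day 4 the Dlk1-Dio3 imprinted region, singled out after its values were seen, held several RNAs that were higher with miR-205. Meg3 was higher by 1.66, Rian by 1.31, Mir382 by 1.28 and Mir377 by 1.27, noncoding RNAs made from the maternal chromosome. On the GFP array Rian (5.54), Mir377 (5.51) and Mir382 (6.47) lay below the floor, so their sizes rest on background. Other microRNAs of the region gave smaller differences, Mir134 0.96, Mir154 0.35, Mir127 0.24, Mir411 0.24 and Mir136 0.03, with Mir154, Mir411 and Mir136 below the floor on both arrays. At day 0 Rian passed (1.06) and Meg3 gave 0.58. The paternally expressed growth regulator Dlk1 gave 0.68 at day 4 and the deiodinase Dio3 -0.07.

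Because Dazl, Asz1, Scml2, Tuba3a and Tuba3b had been seen lower with miR-205, germline genes may be lower in general. Among 20 further germline genes measured, 16 were negative at day 4 with a median of -0.50, below all 10000 random lists. With the 5 seen genes, 4 of 25 were called lower and the median was -0.58; the called genes were all among those seen, so the count of calls tests nothing. At day 0 the median of the 20 was -0.08 (percentile 6.77), and over time it was 0.82 in the GFP line and 0.44 in the miR-205 line. Below the floor on both day 0 arrays lay 11 of the 20, so the day 0 median rests largely on background. The day 4 median goes with a wider difference in the group and does not separate miR-205 from another difference between the lines.

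Because Tbx20, Hand1, Hand2, Foxf1, Bmp4, Bmp5, Postn and Tnni1 had been seen higher with miR-205 at day 4, a wider set of heart and allantois mesoderm genes may be higher. Among 14 further genes of this kind, 12 were positive at day 4 with a median of 0.52 (percentile 100). None of the 14 was called, and the set was uneven. Nkx2-5 (0.007), Actc1 (0.11), Gata5 (0.11) and Myl4 (-0.04) differed little, and Tbx4 was negative (-0.82). Below the floor on both arrays lay 3 of the 14, Gata5 among them. With the 8 seen genes, 8 of 22 were called higher and the median was 0.81; these 8 are the genes seen, so here too the count of calls tests nothing. At day 0 the median of the 14 was -0.11, and 7 of the 14 lay below the floor on both arrays, so it rests partly on background. The day 4 median, too, does not separate miR-205 from another difference between the lines.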
